A study of Nannochloropsis oceanica with 15 samples.

How the data were processed

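The samples were wild-type IMET1 cells of Nannochloropsis oceanica grown in column bioreactors under continuous light of 80 ± 5 µmol photons per square metre and second at 25 °C. They were bubbled with air (0.04% CO2) at 0.6 volumes per volume and minute, in a medium with 427.5 mg/L of sodium nitrate, per the series' design text. Samples were taken in white light at 0 h and after 12 h and 24 h of red or blue light. RNA was extracted with Trizol, and libraries were made from 1 µg of total RNA with a TruSeq kit, per the labels' protocols.

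The authors deposited 5 tables of FPKM (fragments per kilobase of model, divided by a total per library that the notes do not define), 1 per group with a column per library, and a table of gene models. The submitters' processing notes name TopHat, TopHat2 2.0.4 and Cufflinks 2.0.4, with no settings. The gene models are named IMET v2, and the processing notes add no genome build. The deposited models number 9756, each with 1 transcript, on 284 scaffolds; their source column names AUGUSTUS, and 1 model, DGAT1A, is marked manual. A column name was repeated in the table of red 12 h, and the third library was taken through the sample name that the same rows carry. The FPKM values are not scaled to a common median: the medians of the 15 libraries ran from 17.8 to 25.0.

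Depth was recovered from the values. In each library an FPKM times the exon length less the mean fragment length, times a library constant, gave a whole number of fragments. Within a tolerance of 0.1 this held for 100% of the 357 to 1874 values per library that stood for at most 30 fragments in models with an effective length of at least 500 nt. The recovered fragments in genes numbered 3130000 to 6440000 per library, and the mean fragment length to 129.5 to 149 nt. They served to check replicates, to give the counts behind low values and as an added alternative, since FPKM is not a count and no count model is the main test.

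The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with lmFit, contrasts and eBayes with a trend. All 15 libraries entered 1 fit with a mean per group, since groups of 3 alone estimate the spread poorly. Genes with an FPKM of at least 1 in at least 3 libraries were tested, which left 9601. Tests were two-sided, with Benjamini-Hochberg adjustment per comparison and a threshold of 0.05. The 8 comparisons were each colour and time against white 0 h, blue against red at each time, and 24 h against 12 h in each colour, with the interaction of light and time. The tests, the gene lists and most alternatives were fixed before the data were examined. Overlaps of calls were compared with n1 × n2 / N, and for comparisons that share the white libraries with 50 simulations of unchanged groups. Permutations and Fisher's exact tests on gene positions used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

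The procedure was tested on simulated data with 200 genes changed among 9601. Over the 8 comparisons it recovered 65% (blue 24 h against blue 12 h) to 78.5% (red 12 h against white) of changes of 1 on the log2 scale, 94.5% to 99.5% of changes of 2 and 0% to 10% of changes of 0.5. It also called 0 to 14 of the unchanged genes. All simulated libraries of a gene had the same spread, whereas red 24 h library 1 lay much further from its group than any other library. These rates therefore need not hold for the real comparisons.

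The 25 gene lists were to be matched by name. The reference table of 160 organelle genes, from assembly ASM5162214v2, matched 0 of the IDs, and the files pair IDs with no names apart from DGAT1A. So 24 lists had no member, the list of triacylglycerol assembly had 1 (DGAT1A), and no gene set test was run. For this case the rule for named genes allowed 2 genes that rose and 2 that fell. They are those with the largest change in any comparison among genes that passed, with groups that did not overlap and a mean of at least 10 FPKM in a group, besides any gene of a list.

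The alternatives fixed beforehand were a pseudocount of 0.1, no filter, a filter at 5 FPKM, quantile normalization, scaling to the same median, scaling to the same sum without the 50 most abundant genes, a fit of only the groups compared, the replicate number as a block, eBayes without the trend, limma's array weights, a 2-fold minimum and leaving out each of the 15 libraries. Chosen after seeing the data were leaving out white 0 h library 1 and red 24 h library 1 together, removing each library's trend with exon length (loess, span 0.5) and limma's voom on the recovered fragments.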

Results

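Nannochloropsis oceanica is a single-celled marine alga that stores much of its carbon as oil. In wild-type cells of strain IMET1, RNA sequencing measured how gene expression changed when white light was replaced by red or by blue light. The 15 libraries formed 5 groups of 3. White 0 h was sampled at the switch, and red 12 h, red 24 h, blue 12 h and blue 24 h were sampled 12 h or 24 h after it. No white-light library from 12 h or 24 h was analysed here, so every difference from white 0 h combines light colour with time. A difference between blue and red at the same hour is free of time.

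Each library gave an FPKM value for 9756 gene models, and between 26 and 128 of them were listed at 0. The fragments recovered from the steps of the low values numbered 3130000 to 6440000 per library. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. No pair of libraries within a group differed by less than sampling noise. The chi-square per degree of freedom of their fragments ran from 1.32 to 1.95 in the 4 groups other than red 24 h. In red 24 h it was 5.32 for libraries 2 and 3, and 52.0 and 84.5 for the pairs with library 1.

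White-light cells stood apart from all the others. The first principal component held 65.8% of the variance and separated the 3 white libraries from the 12 red and blue ones. Across genes, the mean correlation of log2(FPKM + 1) between a white library and another library was 0.773, against 0.991 within the white group. Red 24 h library 1 was separated on the second component, which held 17.6% of the variance. Its mean correlation with its own group was 0.917, while libraries 2 and 3 correlated at 0.984 with each other. It also had the shortest mean fragment, 129.5 nt, and its 100 most abundant genes took 38.4% of the FPKM sum, against 29% and 27.2% in libraries 2 and 3. White 0 h library 1 had lower FPKM values than the other white libraries. Its median was 20.3 against 24.7 and 25.0 in white libraries 2 and 3, and its sum 430453 against 523387 and 528814.

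**Figure D1:**
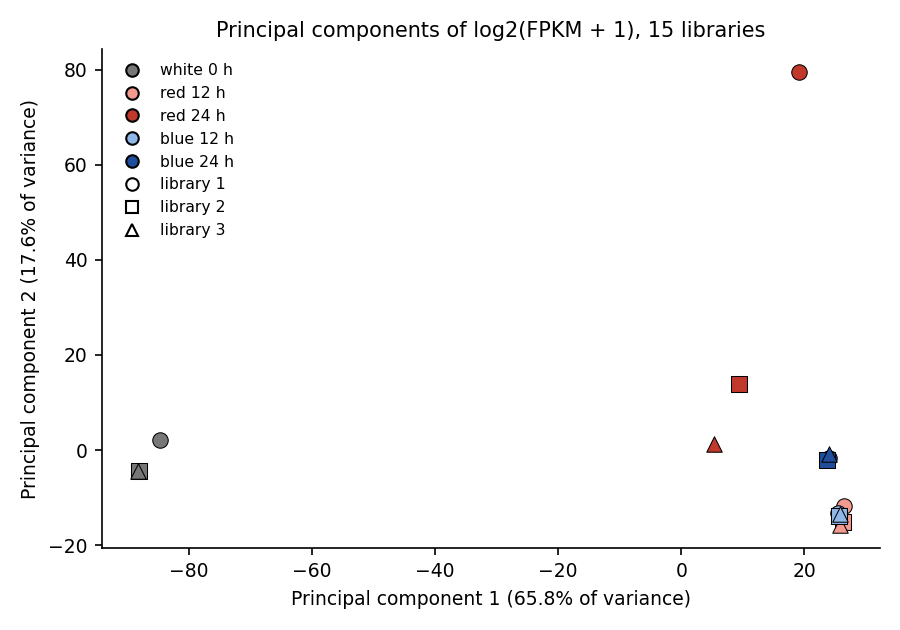
Principal components of log2(FPKM + 1) over the tested genes, with component 1 (65.8% of the variance) on the x axis and component 2 (17.6%) on the y axis. Each symbol is a library, coloured by group; the 3 white libraries lie left of the other 12, and red 24 h library 1 lies above the rest.

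The first comparison asks what changed from white light to each colour. Most of the tested genes passed the test in each of the 4 comparisons, and the large changes were mostly decreases. Of 9601 genes, 5512 changed in red 12 h (3150 rose, 2362 fell) and 5657 in red 24 h (2766 rose, 2891 fell). In blue light 5614 changed at 12 h (3105 rose, 2509 fell) and 5276 at 24 h (2982 rose, 2294 fell). At least 4-fold decreases numbered 702 to 851 per comparison, against 47 to 109 increases of that size. Genes that fell at least 2-fold in all 4 comparisons numbered 1185, and their median expression was 27.1 FPKM in white, 3.40 in red 12 h, 5.05 in red 24 h, 3.47 in blue 12 h and 3.59 in blue 24 h. Genes that rose at least 2-fold in all 4 numbered 323, with medians of 31.8 FPKM in white and 91.0 to 101.5 FPKM in the other groups.

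The split into rises and falls depended on the scale of the values. As deposited, 48.9% of the calls were rises in red 24 h, 55.3% in blue 12 h and 56.5% in blue 24 h. With every library at the same sum without the 50 most abundant genes these shares were 29.9%, 45.0% and 43.2%, and the median change of all genes in red 24 h moved from -0.01 to -0.31 on the log2 scale. With the length trend of each library removed, rises made up 60.4% of the red 24 h calls, and with voom weights they made up 45.8% of the blue 24 h calls. The set that rose in all 4 comparisons held 641 genes after quantile normalization, 493 with the length trend removed and 165 at the same sum, while the set that fell held 1045 to 1359 genes in the 27 alternatives run.

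**Figure D2:**
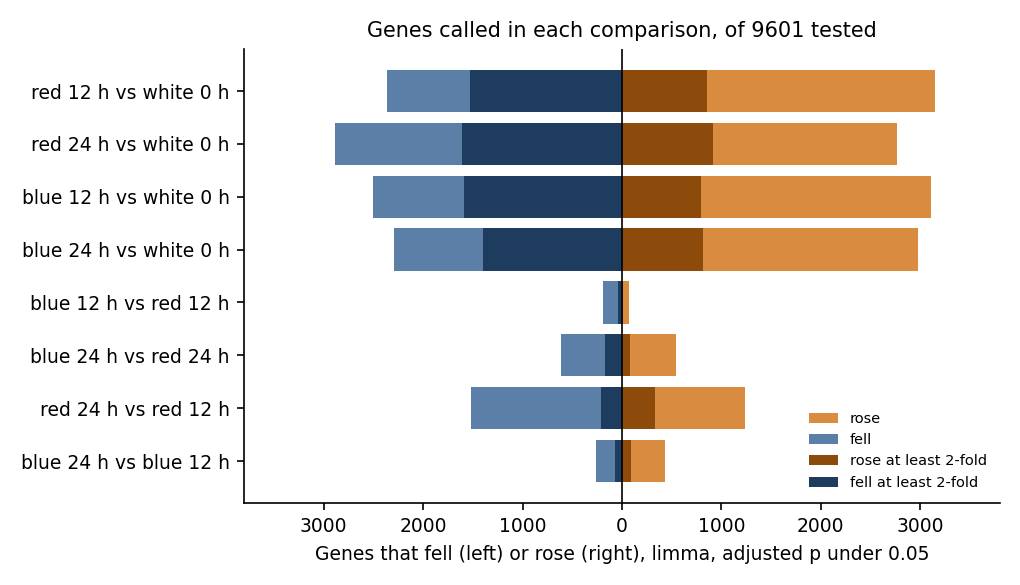
Number of genes called in each of the 8 comparisons (limma, adjusted p under 0.05), with falls to the left of 0 and rises to the right. Dark bars are the calls of at least 2-fold; relative to white they hold 1400 to 1613 falls and 794 to 919 rises.

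Among the named genes the largest falls were on scaffold00043. The gene scaffold00043.g1553 (positions 14516 to 19694, plus strand, 9 exons) fell from 216 ± 27.1 FPKM (SD, n = 3) in white to 3.87 ± 0.335 in red 12 h and 2.43 ± 0.173 in blue 24 h. Its log2 change in blue 24 h was -5.98 ± 0.16 (SE; limma adjusted p = 1.31e-12), an 88.9-fold lower mean FPKM. The gene scaffold00043.g2109 (1666228 to 1666775, plus strand, 1 exon) fell from 147 ± 14.4 FPKM in white to 2.46 ± 1.15 in red 12 h and 1.73 ± 0.518 in blue 24 h, where it rested on 3 to 5 fragments per library. Its log2 change in blue 24 h was -5.77 ± 0.35 (adjusted p = 2.88e-09). Both changes kept their direction and passed in all 28 alternatives run, as did the rises of the next 2 genes relative to white. The scaffold00043 genes lie near opposite ends of their scaffold. scaffold00043.g1553 is in a run of 6 neighbouring genes that fell (2217 to 22640), and scaffold00043.g2109 ends where the last gene model ends. For falls near scaffold ends, lost DNA and joint lowering of the genes cannot be told apart here.

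The largest rises were in scaffold00354.g10128 (397542 to 401706, plus strand, 1 exon) and scaffold00210.g6057 (1 to 971, minus strand, 1 exon). The first stood at 0.530 ± 0.0927 FPKM (SD, n = 3) in white and at 36.3 ± 2.63 in red 12 h, a 68.4-fold difference (log2 change 4.61 ± 0.26 SE, limma adjusted p = 9.77e-10). The second stood at 4.86 ± 1.49 FPKM in white and reached 144 ± 5.84 in blue 24 h, a 29.6-fold difference (log2 change 4.66 ± 0.24, adjusted p = 4.08e-10). Folds are ratios of mean FPKM, while log2 changes are of FPKM + 1 and so are smaller for low genes. The files pair none of these IDs with a gene name.

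**Figure D3:**
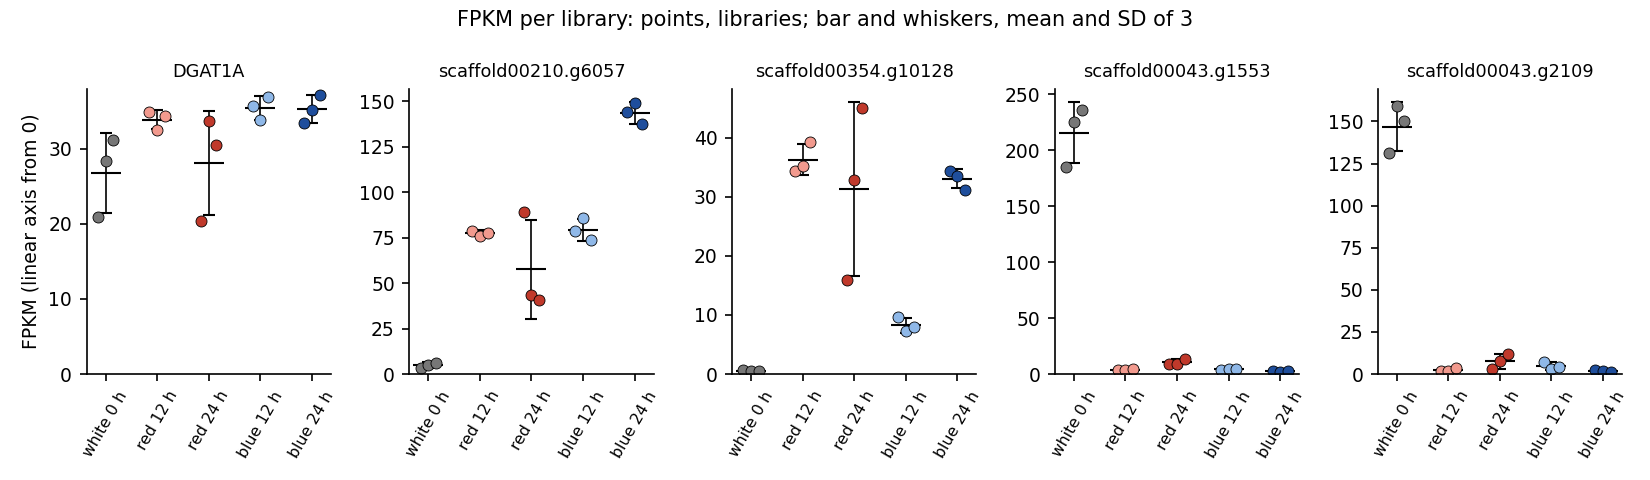
FPKM per library (y axis, linear from 0) in the 5 groups (x axis) for the named genes; points are libraries, and bars with whiskers are the mean and SD of 3. The scaffold00043 genes are high only in white, scaffold00210.g6057 reaches 144 FPKM in blue 24 h, and DGAT1A lies between 20.4 and 37.1 FPKM in every library.

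DGAT1A is the only gene with a name in the files. It encodes a diacylglycerol acyltransferase, the enzyme class that makes triacylglycerol, the storage oil, from diacylglycerol. The model (isotig00738, 1 to 2030) had 26.8 ± 5.30 FPKM (SD, n = 3) in white, 33.9 ± 1.25 in red 12 h, 28.1 ± 6.92 in red 24 h, 35.4 ± 1.55 in blue 12 h and 35.2 ± 1.86 in blue 24 h. White libraries 1, 2 and 3 held 20.9, 28.3 and 31.1 FPKM, and library 1 also had the lowest median FPKM of the white libraries over all genes. None of the differences from white passed the limma test over all genes. The lowest adjusted p was 0.0528, in blue 12 h, with a log2 difference of 0.41 ± 0.17 (SE), and all 3 blue libraries were above all 3 white ones. DGAT1A was the 1 matched member of the 25 gene lists fixed before the data were examined, so adjusted over the list alone its p was the raw value, 0.0312 in blue 12 h, 0.0340 in blue 24 h and 0.0619 in red 12 h. The blue 12 h difference passed in 12 of 28 alternatives (adjusted p 9.29e-05 to 0.259). Those included leaving out red 24 h library 1 (0.00281), red 24 h library 2 (0.0398), red 24 h library 3 (0.0480) or white 0 h library 3 (0.0298), whereas without white 0 h library 1 the difference was 0.25 (0.239). The blue 24 h difference passed in 11 (0.000180 to 0.364), with the call gained without red 24 h library 1 (0.00345), red 24 h library 2 (0.0457) or white 0 h library 3 (0.0337), whereas without white 0 h library 1 it was 0.24 (0.260). The red 12 h difference passed in 7 (0.000418 to 0.382), among them the fit without red 24 h library 1 (0.00956), and without white 0 h library 1 it was 0.18 (0.382).

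The genes that fell were not spread evenly along the scaffolds. The following regions were chosen after their values were seen. At the end of scaffold00295, 29 tested genes in a row, from 1075109 to 1137324, fell at least 2-fold in all 4 comparisons. This run reached the last gene model of the scaffold, and elsewhere on it 42 of the other tested genes fell. The median gene of the run had 50.7 FPKM in white, 1.17 in red 12 h, 7.58 in red 24 h, 2.12 in blue 12 h and 2.40 in blue 24 h. A run of 15 genes closed scaffold00026 in the same way (1457258 to 1494702). Its medians were 21.3 FPKM in white, 0.785 in red 12 h, 2.49 in red 24 h, 0.976 in blue 12 h and 0.796 in blue 24 h. In all, 11 runs of 5 or more genes held 95 genes, and 5 of them reached the last model of their scaffold. Neighbouring genes both fell in 317 of 9320 pairs, 2.14 times the 148 expected when the calls were shuffled within scaffolds (permutation p = 1e-05, one-sided, the smallest that 100000 permutations can give; adjusted over 5 classes of pair 1e-05). The longest run in 10000 shuffles was 8 genes. Coordinates are those of the deposited gene models, which are named IMET v2.

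**Figure D4:**
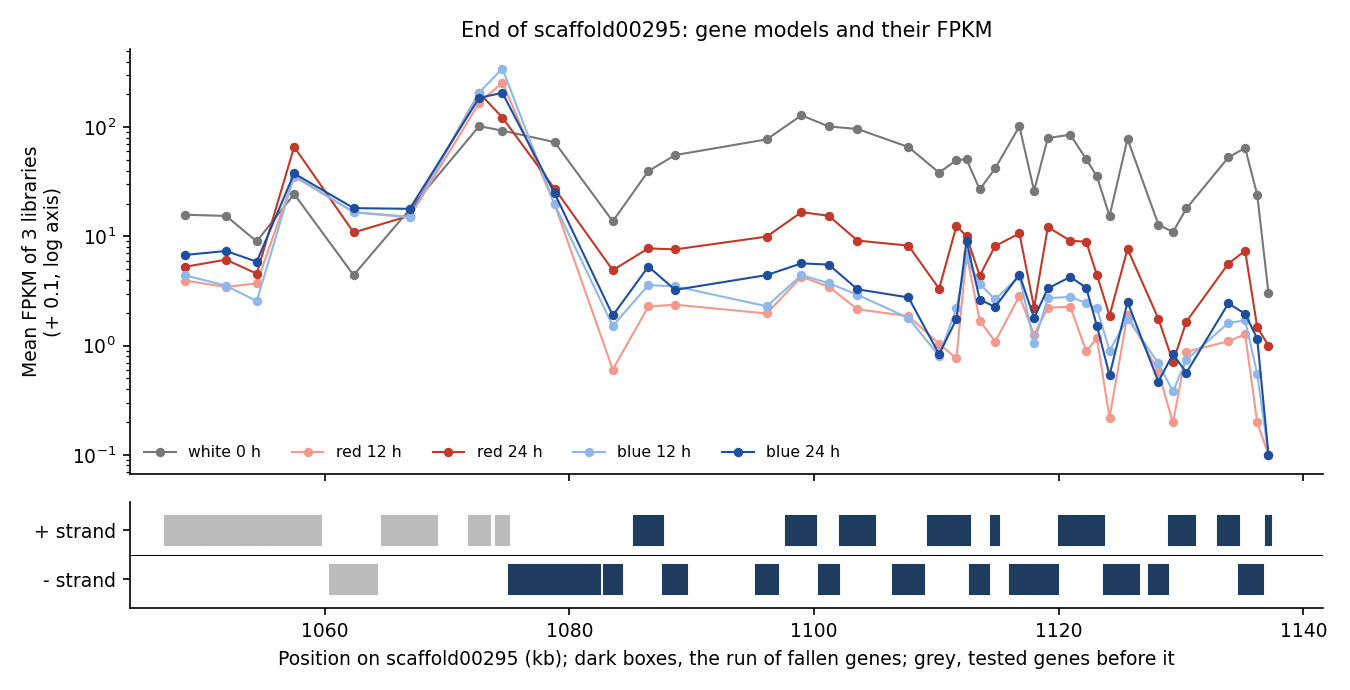
Mean FPKM of 3 libraries per gene (upper panel, log axis, 0.1 added) along the end of scaffold00295 (x axis, kb), with the gene models by strand below. Dark boxes are the 29 genes of the run and grey boxes the tested genes before it; in the run the median gene has 50.7 FPKM in white, 1.17 in red 12 h and 7.58 in red 24 h.

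Whether red and blue light met the same response was asked by setting their changes from white side by side. At 12 h, 2626 genes rose in both colours and 2185 fell in both, and 6 went opposite ways. At 24 h, 2198 rose in both, 2100 fell in both and 10 went opposite ways. Independent lists of these sizes would share 1019 rises and 617 falls at 12 h, and 859 rises and 691 falls at 24 h. The correlation of the changes across genes, which are not independent replicates, was 0.97 at 12 h and 0.921 at 24 h. Both colours share the white libraries. In the simulation of unchanged groups, all 15 libraries were redrawn as independent noise around each gene's white mean. The correlation was then 0.498 at 12 h and 0.501 at 24 h, with 0 shared calls. Such noise holds no shift common to the 3 real white libraries, so it cannot exclude one. The covariance was 1.32 at 12 h against 0.0249 simulated, and 1.12 at 24 h against 0.0251. The 3 white libraries cannot be split into parts of 2 or more, so part of the overlap may come from them.

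The second comparison asks how blue differs from red at the same hour. At 12 h most of the genes that passed were lower in blue. The gene scaffold00354.g10128 stood at 8.26 ± 1.25 FPKM (SD, n = 3) in blue against 36.3 ± 2.63 in red, 4.39-fold lower (log2 difference -2.02 ± 0.26 SE, limma adjusted p = 0.000795), and it passed in all 28 alternatives run. In all, 265 genes passed, of which 69 were higher and 196 lower in blue. Of the 196 lower genes, 125 had risen and 25 had fallen in red relative to white, and in blue 65 had risen and 73 had fallen. Of the 69 higher genes, 21 had risen and 29 had fallen in red, and in blue 40 had risen and 17 had fallen. Over all 9601 tested genes, 3150 rose and 2362 fell in red 12 h, and 3105 rose and 2509 fell in blue 12 h. The same red and blue libraries enter both the choice and these counts. Choosing genes lower in blue thus favours rises in red and falls in blue by itself.

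The 12 h count and its split depended on the other libraries. Leaving out 1 of the 3 red 12 h libraries gave 82, 89 and 75 genes, leaving out 1 of the 3 blue 12 h libraries gave 94, 99 and 90, and leaving out blue 24 h library 3 gave 172. Without red 24 h library 1, which takes no part in the comparison but adds to the shared estimate of the spread, 1540 genes passed, 659 higher and 881 lower in blue. With only these 6 libraries in the fit 2444 genes passed. Rises made up 26.0% of the calls as deposited, 39.0% after quantile normalization, 47.6% at the same median, 48.6% with the length trend removed and 42.2% with voom weights.

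At 24 h both scaffold00043 genes were lower in blue and scaffold00210.g6057 was higher. Blue exceeded red in scaffold00210.g6057, with 144 ± 5.84 FPKM (SD, n = 3) against 57.6 ± 27.3 (log2 difference 1.40 ± 0.24 SE, limma adjusted p = 0.00207). The red libraries held 89.1, 43.2 and 40.6 FPKM, and with only the 6 libraries of the comparison in the fit the adjusted p was 0.114. Blue was lower in both scaffold00043 genes, scaffold00043.g1553 by -1.72 ± 0.16 (adjusted p = 2.72e-05) and scaffold00043.g2109 by -1.52 ± 0.35 (adjusted p = 0.0141). The latter no longer passed without blue 24 h library 2 (0.0524) or blue 24 h library 3 (0.0658), nor with only the 6 libraries in the fit (0.180). In all, 1153 genes passed, 544 higher and 609 lower in blue. Both groups held genes that went each way from white. Of the 609 lower genes, 325 had fallen and 228 had risen in red, and in blue 371 had fallen and 151 had risen. Of the 544 higher genes, 199 had fallen and 99 had risen in red, and in blue 37 had fallen and 297 had risen. Over all 9601 tested genes, 2766 rose and 2891 fell in red 24 h, and 2982 rose and 2294 fell in blue 24 h. As at 12 h, the choice of genes and the counts from white share the red and blue libraries. White-light RNA mixed into the red 24 h libraries, which is not excluded, would move genes there toward their white level. It could thus add to the 1153 calls.

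Which hour differed more depends on the libraries in the fit. With all 15, 265 genes passed at 12 h and 1153 at 24 h. Without red 24 h library 1 they numbered 1540 and 1740. With only the 6 libraries compared the order turned, with 2444 and 44. A fit of only 6 libraries can overstate certainty. In red 12 h against white it gave scaffold00210.g6057 a limma adjusted p of 1.35e-145, beyond what 3 against 3 libraries can bear. The 24 h count was 1740 without red 24 h library 1, 3393 without red 24 h library 3, and 481, 457 and 479 when 1 of the 3 blue 24 h libraries was left out. Rises made up 47.2% of the calls as deposited and 61.7% at the same sum without the 50 most abundant genes. The 12 h and 24 h comparisons share no library, and 38 genes were higher in blue at both hours (3.9 expected; Fisher's exact test, one-sided, odds ratio 21.9, p = 9.3e-30, adjusted over 4 tests 9.3e-30). Another 71 were lower at both hours (12.4 expected, Fisher's exact test, odds ratio 9.36, p = 4.03e-36, adjusted 5.37e-36). Both calls of a gene rest on the same estimate of its spread, and neighbouring genes change together. The expected counts and p-values therefore assume an independence that does not hold. Across all tested genes the differences at the 2 hours correlated at 0.187. The count of shared genes, 109, was 37 to 53 when any 1 of the red 12 h, blue 12 h or blue 24 h libraries was left out, and 524 without red 24 h library 1.

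The third comparison follows each colour from 12 h to 24 h. In red light scaffold00043.g1553 rose from 3.87 ± 0.335 FPKM (SD, n = 3) to 10.4 ± 2.57 (log2 change 1.21 ± 0.16 SE, limma adjusted p = 0.000146), while it stayed far below the 216 FPKM of white. White-light RNA mixed into the red 24 h libraries, which is not excluded, would raise both scaffold00043 genes there, and with them their differences between blue and red at 24 h and between the changes in the 2 colours. Such a mixture could also add to the counts of genes given below for red over time and for the interaction. From red 12 h to red 24 h libraries 2 and 3, the 1185 genes that fell in all 4 comparisons rose by a median log2 of 0.486. Over all tested genes that median was 0.013. In library 1 the 2 medians were 0.094 and -0.287. In blue light scaffold00354.g10128 rose from 8.26 ± 1.25 to 33.0 ± 1.63 FPKM (log2 change 1.89 ± 0.26, adjusted p = 0.000424). The rise of scaffold00043.g2109 in red, from 2.46 ± 1.15 to 7.49 ± 4.22 FPKM (log2 change 1.21 ± 0.35, adjusted p = 0.0225), no longer passed without red 12 h library 1 (0.0648), red 12 h library 2 (0.0917) or red 24 h library 3 (0.0523), nor with the length trend removed (0.0614) or with only the 6 libraries in the fit (0.169). In blue, the rise of scaffold00210.g6057 (0.85 ± 0.24, adjusted p = 0.0442) and the fall of scaffold00043.g1553 (-0.58 ± 0.16, adjusted p = 0.0406) were close to the threshold. Leaving out any 1 of the 6 libraries compared ended both calls, with an adjusted p of 0.0932 to 0.149 for the first and 0.0687 to 0.151 for the second. Leaving out white 0 h library 2 or any red 12 h library ended both as well (0.0628 to 0.0645 and 0.0569 to 0.0601), and leaving out white 0 h library 3 ended the second (0.0521). The first was also lost with a pseudocount of 0.1 (0.0568), at the same median (0.0763) and without the trend (0.0503), and the second at the same sum (0.0527).

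In all, 2751 genes changed in red (1233 rose, 1518 fell) and 695 in blue (430 rose, 265 fell). The red count was 1662, 1332 and 1293 when 1 of the 3 red 12 h libraries was left out, 4470 without red 24 h library 3, and 207 with only the 6 libraries compared in the fit. The blue count was 368, 399 and 360 when 1 of the 3 blue 12 h libraries was left out, and 354, 367 and 354 when 1 of the 3 blue 24 h libraries was left out. Without red 24 h library 1 it was 2450, and with only its 6 libraries in the fit 3591. Rises made up 44.8% of the red calls as deposited, 57.3% at the same median and 27.1% at the same sum, and 61.9% of the blue calls as deposited, 51.8% at the same median and 50.1% with voom weights. The changes in the 2 colours share no library. They had 253 rises in common (55.2 expected, Fisher's exact test, one-sided, odds ratio 11.9, p = 2.51e-120, adjusted over 4 tests 1e-119) and 160 falls (41.9 expected, odds ratio 8.95, p = 3.47e-63, adjusted 6.94e-63), and 22 genes went opposite ways. Here too the calls share each gene's estimate of the spread and the genes are not independent, which these tests assume. Across all tested genes the changes in the 2 colours correlated at 0.479. The count of shared genes, 413, was 223 to 264 when any 1 of the blue libraries or red 12 h library 2 was left out, and 1241 without red 24 h library 1.

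A test of the difference between these 2 changes found 219 genes, of which the change from 12 h to 24 h was more positive in blue for 71 and more negative for 148. For scaffold00354.g10128 it was more positive in blue by 2.21 ± 0.36 on the log2 scale (SE; limma adjusted p = 0.00431), and for scaffold00043.g1553 more negative, -1.79 ± 0.23 (adjusted p = 0.000878). Both passed in all 28 alternatives run. At the same sum without the 50 most abundant genes, 44.9% of the calls were positive, against 32.4% as deposited. The count was 751 without red 24 h library 1 and 1044 without red 24 h library 3, where 61.8% of the calls were positive, and it was 121 to 144 when any 1 of the red 12 h, blue 12 h or blue 24 h libraries was left out.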

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

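Among the tests in this part, those of an exchanged label, of reads from adjacent genes, of scaffolds from another organism, of missing DNA copies, of the FPKM scale and of other splits of the libraries, and the choice of genes by blue light or by red 12 h, were chosen only after the results were seen.

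The change from 12 h to 24 h differed between red and blue light in 219 genes by the interaction test in limma, and each of the 4 named IDs was among them. The difference (blue minus red, log2) was 1.37 for scaffold00210.g6057 (adjusted p = 0.0499), 2.21 for scaffold00354.g10128 (0.00431), -1.79 for scaffold00043.g1553 (0.000878) and -2.22 for scaffold00043.g2109 (0.0302). The call for scaffold00210.g6057 held in 10 of 28 alternatives (adjusted p 1.08e-09 to 0.123) and ended when any 1 red 12 h, blue 12 h or blue 24 h library was left out (0.0888 to 0.123), and without white 0 h library 2 (0.0755), white 0 h library 3 (0.0545) or red 24 h library 2 (0.0944). It also ended with a pseudocount of 0.1 (0.0641), no filter (0.0507), the same median (0.111), only the groups compared (0.0642) and no trend (0.0540). The call for scaffold00043.g2109 held in 17 of 28 (3.53e-06 to 0.0946). It ended without white 0 h library 2 (0.0515) or 3 (0.0518), red 12 h library 1 (0.0783) or 2 (0.0946), red 24 h library 2 (0.0616), blue 12 h library 1 (0.0899) or 3 (0.0668), or blue 24 h library 2 (0.0752) or 3 (0.0879), at the same sum (0.0663) and with only the groups compared (0.0809). With the effects of light and of time removed from each gene, 1 of 100 splits of the 12 red and blue libraries, the real one, gave 219 genes or more. The highest of the others, drawn at random, gave 0. The real grouping stood apart from the random ones, but these mix libraries of different groups. What remains of the real differences then enters their spread and lowers their counts, so chance in the grouping is not excluded. A chance difference between cultures cannot be judged from libraries that may be technical replicates. With the effects of light and of time left in, where they enter the spread of the other splits, 2 of 100 gave as many, the real one included. The highest other gave 224. Left-out libraries moved that count from 121 (red 12 h library 3) to 1044 (red 24 h library 3), with 751 without red 24 h library 1, 143 and 129 without red 12 h libraries 1 and 2, 131, 144 and 140 without blue 12 h libraries 1, 2 and 3, and 136, 140 and 140 without blue 24 h libraries 1, 2 and 3.

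For the 8 comparisons of 3 against 3, the 6 libraries can be split in 10 ways, too few for a share under 0.05. In each, 1 of the 10 splits, the real one, gave as many genes as observed (5512, 5657, 5614, 5276, 265, 1153, 2751 and 695 in the order of the report), and the highest of the others gave 0. The other splits mix libraries of both groups, so the real differences enter their spread and lower their counts. The 0 is therefore no estimate of how many genes would be called by chance.

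Red 24 h library 1 lay far from libraries 2 and 3, which no group of the design accounts for. Relative to them its genes shifted with exon length, from a median of 0.16 on the log2 scale in the shortest sixth of the genes to -0.56 in the longest. Removing the length trend left its mean correlation with its own group at 0.921 (0.917 before), and leaving out the 100 most abundant genes left 0.908, so neither accounts for the whole distance, and its highest mean correlation with another group was 0.899, which argues against a label exchanged within the series. Damage to the RNA or a different culture stays open, and no biological explanation was tested.

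Neighbouring genes fell together relative to white light, as in the run of 29 genes at the end of scaffold00295. Neighbours at least 1000 nt apart both fell 2.06 times as often as their own share of fallen genes gives, which argues against reads shared with an adjacent gene. On each of the 63 scaffolds with 5 or more tested genes, at most 35.3% of them fell. For these scaffolds this argues against whole scaffolds of another organism. The rest of the 284 scaffolds with a model were too small for this check, which also cannot judge a part of a scaffold, such as its end. The run kept a median of 2.67% of its white level in red 12 h, with 0 to 26.9% in its genes. In red 24 h the median was 12.7%, with 5.61% to 37.4% in its genes. Missing DNA alone would not give such a later rise. White-light RNA mixed into the red 24 h libraries, which is not excluded, could give it. Segments of DNA missing from most cells of the red and blue cultures and joint silencing of the genes cannot be told apart here, since no DNA was measured.

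In 95 genes, chosen on white and blue alone for at least 30 FPKM in white and over 16 times less in blue 12 h and blue 24 h, the red 24 h libraries kept more of the white level than the red 12 h libraries. Their medians were 8.27%, 10.6% and 11.3% of white, against 3.58%, 3.29% and 3.41% in red 12 h, and with every library at the same median the ratio of red 24 h libraries 2 and 3 to red 12 h was 3.17 (bootstrap SD 0.186), which argues against the FPKM scale. A mixture with white-light RNA may give this, and would return 1 common share of the gap to white: libraries 2 and 3 regained 16.4% (SD 1.52), 11.3% (SD 1.49), 8.49% (SD 0.78) and 8.25% (SD 0.32) in genes 2 to 4, 4 to 8, 8 to 16 and 16 or more times lower in red 12 h, where blue 24 h regained 13.3%, 1.49%, -0.09% and 0.09% in the classes of blue 12 h, and library 1 ran the other way (-5.36%, 0.64%, 2.64% and 5.6%). The difference set for the test before it was run, 16 or more minus 4 to 8 times, was -3.08 percentage points, past its bound of 3 by less than its spread, and with classes taken from blue 12 h both gave close to the same (8.28% and 8.25%) but genes 2 to 4 times lower gave 14.5% (SD 1.33), so a mixture is neither shown nor excluded. A partial return toward the white-light state stays open too, since the median log2 change from red 12 h to libraries 2 and 3 of risen genes was -0.074 (SD 0.014) when they were chosen in red 12 h, short of the -0.1 set beforehand although that choice alone makes genes fall back, -0.009 (SD 0.015) when chosen in blue 12 h and 0.088 (SD 0.012) in blue 24 h.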

How the results depend on the processing

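The 3 alternatives chosen only after the data were seen were leaving out white 0 h library 1 and red 24 h library 1 together, removing the length trend, and voom weights. These libraries are called doubtful here, white 0 h library 1 for its low FPKM values and red 24 h library 1 for its distance from its group. Of 1341 recomputed values for named genes and gene sets, 1217 kept their direction and their side of the threshold or stayed within 1.5 times. Of the rest, 64 no longer passed, 45 newly passed, 12 reversed and 3 moved. The 12 reversals were all of differences that did not pass. DGAT1A in red 24 h against white (0.06) was -0.249 at the same sum, -0.104 without white 0 h library 1, -0.081 without red 24 h library 2, -0.011 without red 24 h library 3 and at most 0.267 (without red 24 h library 1) with 1 library left out, and its change in blue from 12 h to 24 h (-0.01) was 0.02 without blue 12 h library 3, 0.029 without blue 24 h library 1 and at lowest -0.045 (without blue 24 h library 3). The gene scaffold00210.g6057 in blue against red at 12 h (0.03) was -0.009 after quantile normalization, -0.029 without blue 12 h library 2 and at most 0.078 (without blue 12 h library 3). The gene scaffold00354.g10128 in blue against red at 24 h (0.19) was -0.217, and its change in red from 12 h to 24 h (-0.32) was 0.087, without red 24 h library 1 and also without both doubtful libraries; without red 24 h library 3 they were 0.508 and -0.637. Where it is not evident from the construction (fewer libraries, or a higher bar), the cause was not tested.

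Counts of changed genes relative to white stayed within 1.5 times in all alternatives except the 2-fold minimum, which left 2378 (red 12 h), 2532 (red 24 h), 2382 (blue 12 h) and 2216 (blue 24 h), and the fit of only the 2 groups, which left 3660 in red 24 h. The other counts moved further. Blue against red at 12 h (265) became 605 after quantile normalization, 616 at the same median, 2444 in the fit of only its groups, 2946 with array weights, 49 with the 2-fold minimum, 2344 without both doubtful libraries, 727 with the length trend removed and 777 with voom. Blue against red at 24 h (1153) became 1744, 1820, 44, 6378, 257, 2519, 2150 and 1745 in that order. Red 24 h against red 12 h (2751) became 207 in the fit of only its groups, 6952 with array weights and 537 with the 2-fold minimum. Blue 24 h against blue 12 h (695) became 1254, 1175, 3591, 4018, 166, 3285, 1283 and 1404 in the first order. The interaction (219) became 425 after quantile normalization, 497 at the same median, 4231 with array weights, 1361 without both doubtful libraries, 570 with the length trend removed and 495 with voom. The overlap of blue against red at both hours (109) became 273, 251, 890, 332 and 311, and that of the changes with time (413) became 756, 744, 1813, 767 and 849, for quantile normalization, the same median, both libraries left out, the length trend and voom. Array weights gave red 24 h library 2 a weight of 129. The mean correlation of white with the other libraries (0.773) was 0.753 with a pseudocount of 0.1, 0.793 with no filter, 0.746 with the filter at 5 FPKM and 0.774 after quantile normalization.

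Leaving out 1 library at a time, with the spread pooled over the rest, gave 75 to 1540 genes for blue against red at 12 h, 457 to 3393 at 24 h, 1293 to 4470 for red over time, 354 to 2450 for blue over time, 121 to 1044 for the interaction, 37 to 524 for the overlap at both hours and 223 to 1241 for the overlap over time. The lowest came from leaving out a library of the groups compared, and the highest from leaving out red 24 h library 1 or 3. Without red 24 h library 1 all calls but 1 (in blue 12 h against white) were kept in the comparisons without red 24 h, and all in the interaction. Of the calls that use red 24 h, 93.5% were kept against white, 91.3% against blue 24 h and 82.3% against red 12 h.

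The labels give every group replicates 1 to 3. Deviations from the group means of same-numbered libraries correlated at -0.06 to 0.15, above 0.1 in 2 of 30 pairs. The mean was 0.014, against -0.007 for libraries of other numbers. Of the 15 libraries, 9 were closest to their own number, more than an even spread over the 3 numbers gives. Any pairing by number is therefore weak, but it is not excluded. With the replicate number as a block the counts were 5563, 5727, 5657 and 5332 relative to white, 241 and 1199 for blue against red, 2870 and 641 over time and 219 for the interaction. With the block, scaffold00210.g6057 lost its change in blue from 12 h to 24 h (adjusted p = 0.0648 in limma) and its interaction (0.0742), and DGAT1A passed in blue 12 h (0.0367) and blue 24 h (0.0420) against white. Count models planned for count tables were not run, since the values are FPKM, and the planned gene set tests were not run, since no list had 3 members. At 3130000 to 6440000 fragments a library, values of a few FPKM in short genes rest on few fragments.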

Other observations

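All tests in this part were chosen only after the results were seen.

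Genes near the ends of scaffolds fell more often. On the 29 scaffolds with at least 100 tested genes, 186 of 789 genes within 50 kb of an end (23.6%) fell at least 2-fold in all 4 comparisons with white, against 833 of 7545 further away (11%). An end here is the first position of a scaffold or the end of its last gene model, since the gene models give no scaffold lengths. Rotating the calls along each scaffold 100000 times gave a permutation p = 1e-05 (one-sided, the smallest possible; adjusted over 3 tests 1.5e-05). Without the 2 scaffolds that hold the longest runs the shares were 18.9% and 10.9% (permutation p = 1e-05, adjusted 1.5e-05). Genes that rose showed no such excess, with 2.41% near the ends and 3.55% further away (permutation p = 0.966). A candidate explanation is that stretches near chromosome ends are lowered together when white light ends or with time in culture; scaffold ends need not be chromosome ends, and the test cannot separate this from DNA lost at the ends.

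The run at the end of scaffold00295 also differed in gene structure. Of its 29 models, 20 had 1 exon (69.0%), against 30.5% of the other tested genes (Fisher's exact test, two-sided, odds ratio 5.05, p = 2.38e-05). The run was picked for its length and its models are neighbours, so the p-value assumes an independence that does not hold. In the other runs of 5 or more genes the share went from 1 of 7 models (scaffold00259) to 4 of 6 (scaffold00026, from 341139 to 353835). Among all 1185 genes that fell in the 4 comparisons the share was 32.1%, close to the 30.5% of the rest.

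Adjacent genes changed together most when they pointed away from each other. Across 3148 divergent pairs the correlation of log2 changes in red 12 h from white was 0.365, against 0.268 in 3048 tandem pairs and 0.159 in 3124 convergent pairs. For blue against red, in which white has no part, it was 0.193, 0.105 and 0.071 for divergent, tandem and convergent pairs at 12 h. At 24 h it was 0.174, 0.095 and 0.058. The permutation test, two-sided, compared the mean product of standardized changes in divergent and convergent pairs, not the correlations. A larger spread of changes in divergent pairs would also raise that product, and tandem pairs were not tested. It gave permutation p = 3e-05 at 12 h (adjusted over 5 comparisons 5e-05) and 0.00036 at 24 h (adjusted 0.00045). For the change in blue from 12 h to 24 h the correlations were 0.168 in divergent and 0.118 in convergent pairs. The permutation p was 0.216 (adjusted 0.216), so this change did not separate them. Pairs of genes are not independent replicates. A promoter region shared by divergent genes may account for the difference; reads that run past the ends of genes would raise convergent pairs instead.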
